A study of Mus musculus with 30 samples.

How the data were processed

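Gene expression was measured on Affymetrix arrays in mouse primordial germ cells, the embryonic precursors of eggs and sperm. Per the labels' protocols, gonads of embryos with an Oct4(deltaPE)-GFP transgene, a reporter that marks germ cells, were dissociated with trypsin and the GFP-positive cells were sorted. RNA of 500 cells per sample was amplified by whole-transcriptome PCR (TransPlex, with UTP added), fragmented and labelled with biotin. The labels name 2 genotypes on a mixed genetic background: Ring1+;Rnf2+, called control here, and Ring1+;Rnf2delta, called Rnf2delta here. Rnf2 and Ring1 encode the paired ubiquitin ligases at the core of Polycomb repressive complex 1 (PRC1). With stage (E11.5, E12.5, E13.5) and sex they form 10 groups of 3 arrays, and E13.5 was sampled in controls only. The labels do not say whether the 3 arrays of a group came from separate embryos or litters, so p-values measure the spread between these samples, which may be technical.

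The authors deposited log2 signals, 1 for each of 34760 probe sets on each of 30 arrays. The array medians of these log2 values lay between 2.52 and 2.66, so the deposited table was already normalized. R 2.15 and affy 1.36 were used, per the submitters' processing notes; the background correction, the summary of probes into probe sets and the genome build are not given in the sources used here. Scanner files and scan dates were not used here, so no scan batch could be tested. Signal near the array's lower end compresses differences, and the number of arrays limits the precision.

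Probe sets were named from the platform's annotation, and symbols were updated through Entrez identifiers with the RefSeq gene table of assembly GRCm38.p6, which was used for names only. Of the probe sets, 21640 had 1 symbol, 1321 had several and 11799 had none listed. Of those with 1 symbol, 21553 matched through the Entrez identifier and 87 kept the annotation's symbol. Where a gene had several probe sets (954 genes), the one with the highest mean was used, and the mean of all of them was an alternative. A gene was kept if at least 3 arrays exceeded the 40th percentile of their own array. This left 15180 of 19937 genes, and 4757 were removed. Dnmt3l was removed by this filter, and Ddx3y had no probe set with a single symbol. Probe sets without a single symbol were tested separately and enter no gene count.

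Before the data were examined, the tests, the alternatives, 23 gene lists and the rule for named genes were fixed. Each comparison was a contrast in 1 limma fit (limma 3.58.1, R 4.3.3) of all 30 arrays with 1 mean per group, which leaves 20 residual degrees of freedom. The moderated tests were two-sided and adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Interaction contrasts tested whether the genotype effect differed between sexes or between stages. Log2 changes are given with their standard error (SE). The text names Rnf2 and Ring1, the genes past the threshold with the largest rise or fall whose arrays did not overlap between groups (10 each way, shortened to genes of known function), up to 4 members of each list, and a fixed set of germ cell genes (Stra8, Sycp3, Rec8, Dmc1, Rarb, Pou5f1, Nanog, Sox2, Dazl, Ddx4, Nanos2, Xist and Cdkn2a); where fewer than 5 genes passed, the 5 with the smallest p. Members of the fixed set that did not pass are given for the genotype comparisons only. Each gene named as having risen or fallen has all 3 arrays of one group above all 3 of the other, and kept its call in each alternative run and without any 1 array, unless the text says otherwise. Counts of genes hold every gene past the threshold, and their members need not meet these conditions.

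The gene lists were PRC1 subunits, PRC2 subunits, meiotic entry and prophase I, retinoic acid signalling, pluripotency, early primordial germ cell, germline licensing and genome defence, male germ cell differentiation, Hox genes, developmental transcription factors bound by Polycomb in stem cells, cell cycle inhibitors, proliferation, DNA methylation and UHRF1, p53 targets and apoptosis, immediate early and dissociation stress, imprinted genes, Y-linked genes, and markers of supporting, interstitial and mesenchymal, steroidogenic, endothelial, erythroid and macrophage cells. With 3 or more measured genes, 22 lists were tested by camera in limma, which asks whether a list moved relative to other genes, with a preset correlation of 0.01 between genes, and again with an estimated correlation. Camera p-values were adjusted over the lists of a comparison. Counts of list members are given over all genes tested and adjusted over the list alone.

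The fit was tested on simulated data that kept each group's own spread and changed 200 of 15180 genes. Simulated genes varied independently, with 1 draw per comparison, so the false shares compare the fits and need not hold for the real calls. With equal weights for all arrays, 51.0% of the genes called between genotypes at E12.5 in females were false, against 5.98% with array weights and 5.32% with only the compared groups in the fit. The false share was 30.5% for the sexes at E12.5, 29.9% and 29.6% for female E12.5 against E11.5 and E13.5, 22.3% for the sex by genotype interaction at E12.5, and 19.8% for the stage by genotype interaction in females. Array weights gave 5.07%, 8.76% and 10.1% for the sexes and these 2 steps, and 2.33% and 2.22% for the interactions. In the other comparisons the false share was at most 3.95% with equal weights and at most 10.5% with array weights (E13.5 against E11.5 males, 1.96% with equal weights). Of genes changed by 1 on the log2 scale, the fit recovered 88.1% between genotypes at E12.5 in females, array weights recovered 62.7% and the compared groups alone 32.8%, so a call lost in that last fit may reflect its low power. The planned fit was kept, but after this result a rule was added: in a comparison with E12.5 female arrays, rose and fell are used only for genes past the threshold with equal weights and with array weights, and the counts of both fits and of the compared groups alone are printed.

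The alternatives were quantile normalization again, arrays centred on their median, no filter or a stricter filter on dim probe sets (60th percentile), an intensity trend with a robust prior, array weights, only the compared groups in the fit, a minimum of 1.5-fold, the mean of all probe sets of a gene, the replicate number as a block, an estimated correlation for lists, and leaving out each array in turn. In a fit with an array left out, its group of 2 shares the spread estimated from all groups. Chosen after seeing the data were a fit without the 6 E12.5 female arrays, the comparison of E13.5 with E11.5 controls, array weights in the list test, the E12.5 male lists without 1 array, and a fit without small RNA genes. Replicate numbers were checked as pairs through the correlation of deviations from the group means between same-numbered arrays. For E11.5 males all 3 pairs exceeded 0.1 (0.160, 0.124 and 0.104), so there the numbers were taken as possible pairs. In the other comparisons not all 3 did, though E12.5 males gave 0.184, 0.0965 and 0.293. The labels state no pairing, and values come from the unpaired fit unless a block is named.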

Results

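The 30 arrays fell into 10 groups of 3: control and Rnf2delta germ cells of each sex at E11.5 and E12.5, and control germ cells of each sex at E13.5. These are the days on which female mouse germ cells start meiosis and male germ cells turn to the spermatogenic path, and the series addressed how PRC1 times the sexual differentiation of female germ cells. Levels of 15180 genes were compared on the log2 scale. The first 2 principal components held 25.7% and 16.4% of the variance. The 6 E12.5 female arrays stood apart from the other 24. Their mean correlation across genes with their own group was 0.964 to 0.978, against 0.983 to 0.990 elsewhere, where genes are not independent replicates. The interquartile range of their relative log expression was 0.361 to 0.533, against 0.248 to 0.390. Their mean log2 signal over 215 small RNA genes was 3.69 in controls and 3.39 in Rnf2delta, and single arrays of the other groups lay between 3.42 and 3.63. The 2 interquartile ranges overlapped, because E13.5 control female arrays gave 0.361 to 0.390. Of these measures only the correlation set all 6 arrays apart.

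Rnf2 itself was measured by 1 probe set (10358698). In E12.5 males its log2 level was 5.21 to 5.68 on control arrays and 4.09 to 4.46 on Rnf2delta arrays, and it fell by 1.03 ± 0.19 (SE; limma adjusted p = 0.0022). E12.5 females gave 5.08 to 5.71 in controls and 4.47 to 5.0 in Rnf2delta, a change of -0.63 ± 0.19 (adjusted p = 0.029, and 0.012 to 0.36 over the alternatives). This was past the threshold with equal weights and not with array weights, nor without control replicate 1, Rnf2delta replicate 1 or Rnf2delta replicate 3. At E11.5 the female arrays read 4.46 to 4.61 in controls and 3.81 to 4.04 in Rnf2delta (-0.61 ± 0.19, adjusted p = 0.20). E11.5 male arrays read 4.13 to 4.79 and 4.01 to 4.57, so these groups overlapped (-0.31 ± 0.19, adjusted p = 0.80). The probe set may lie outside the deleted part of the gene, in which case its level checks nothing about the genotype. Ring1, the paralogue of Rnf2, changed past the threshold in none of the 4 genotype comparisons; its differences were 0.04, -0.13, -0.10 and -0.33 (± 0.15) in E11.5 females, E11.5 males, E12.5 females and E12.5 males.

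**Figure D1:**
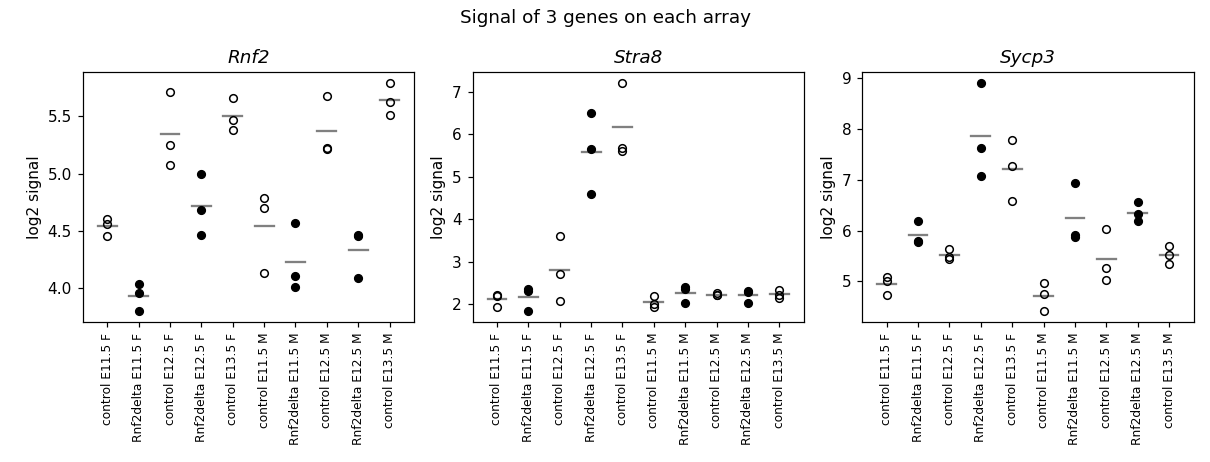
Log2 signal of Rnf2, Stra8 and Sycp3 on each of the 30 arrays (vertical axis) by group (horizontal axis), with open points for control, filled points for Rnf2delta and a bar at each group mean. Stra8 read 4.60 to 6.5 on the Rnf2delta E12.5 female arrays and 2.07 to 3.61 on the control E12.5 female arrays.

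In E12.5 females, Rnf2delta germ cells held more transcript of genes of meiotic entry than controls did. Stra8, the retinoic acid-induced gene required for entry into meiosis, had a log2 level of 2.79 ± 0.77 in controls and 5.59 ± 0.951 in Rnf2delta (SD, n = 3). It rose by 2.79 ± 0.35 (SE, limma adjusted p = 8.5e-06, and 4.5e-07 to 0.048 over the alternatives). Each SE here uses the spread shared by all 10 groups and understates that of these 2. Their median within-group SD was 0.238 in controls and 0.207 in Rnf2delta, against 0.140 to 0.175 in the other groups. Meioc, needed to proceed through meiotic prophase, rose by 2.77 ± 0.27 (adjusted p = 1.6e-07, up to 0.021 over the alternatives). Sycp3 and Sycp1, components of the synaptonemal complex, rose by 2.35 ± 0.33 (adjusted p = 3.0e-05) and 2.13 ± 0.28 (adjusted p = 1.5e-05), each up to 0.038 over the alternatives. Rec8, a meiotic cohesin subunit, rose by 1.57 ± 0.26 (adjusted p = 2.7e-04), a call lost with only the compared groups in the fit (0.15; 1.4e-05 to 0.15 over the alternatives). Dmc1, a meiotic recombinase, did not pass (0.62, adjusted p = 0.11). Of 40 measured genes of meiotic entry and prophase I, 12 rose and 0 fell in both fits. With equal weights 18 were higher and 1 lower, and 26 and 1 adjusted over the list alone. The lower one was Zglp1, a factor of the oogenic programme, at -0.69 with equal weights, named after its value was seen. The list's median was 0.645, and 0.420 without Rnf2delta replicate 1 (camera adjusted p = 1.3e-14); with an estimated correlation adjusted p = 0.111, and the range over its alternatives was 3.1e-17 to 0.111.

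Other genes moved in the same comparison. Cd63, which encodes a tetraspanin, rose by 3.29 ± 0.33 (adjusted p = 1.6e-07), and Tex101, a germ cell surface glycoprotein, by 2.96 ± 0.30 (1.6e-07). Crabp2, a retinoic acid-binding protein, rose by 2.85 ± 0.28, and Taf9b, a subunit of general transcription complexes, and the germ cell genes Xlr and Mael rose by 2.73 ± 0.32, 2.43 ± 0.30 and 1.67 ± 0.26. Of 21 measured genes of germline licensing and genome defence, 6 rose and none fell in both fits, 10 were higher with equal weights and 15 adjusted over the list alone (median 0.658, camera adjusted p = 2.6e-09; adjusted p = 0.111 with an estimated correlation). Pluripotency genes lay lower as a list (29 measured, median -0.269, and -0.412 without control replicate 1; camera adjusted p = 2.8e-06; adjusted p = 0.111 with an estimated correlation, and 9.0e-08 to 0.111 over the alternatives). No single pluripotency gene fell in both fits: 8 were lower with equal weights, 0 with array weights and 10 adjusted over the list alone. Pou5f1 changed by -0.65 ± 0.15 (equal-weight adjusted p = 0.0068, and 0.0020 to 0.20 over the alternatives), Sox2 by -0.67 ± 0.17 (0.011, and 0.0020 to 0.18) and Nanog by -0.58 ± 0.20 (0.064, and 0.0083 to 0.44). Of 18 early primordial germ cell genes 6 were lower with equal weights and none in both fits (median -0.265, camera adjusted p = 0.0020). That list call was lost with an estimated correlation (adjusted p = 0.262) and without Rnf2delta replicate 1 (median -0.22, adjusted p = 0.0897); the median was -0.131 without control replicate 3. The transcripts that fell furthest were small RNAs: Vaultrc5, a vault RNA, by 2.49 ± 0.33 (adjusted p = 1.5e-05), Rny3, a Y RNA, by 1.70 ± 0.22 and Snora73b, a small nucleolar RNA, by 1.40 ± 0.20. Mean small RNA signal was 3.66 to 3.73 on the control arrays here, above all 24 arrays of the other groups (3.42 to 3.63). On the Rnf2delta arrays it was 3.34 to 3.44, with replicates 1 and 2 (3.34 and 3.38) below all 24. Both groups thus deviated, so these falls cannot be assigned to Rnf2delta alone. Group means were also lower in Rnf2delta than in controls in E11.5 females (3.53 against 3.58), E11.5 males (3.47 against 3.60) and E12.5 males (3.49 against 3.55).

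Among chromatin and cell cycle lists in E12.5 females, 1 of 19 PRC1 genes rose in both fits, Cbx8 (1.23 ± 0.18), a chromodomain subunit, and 1 of 11 PRC2 genes, Rbbp7 (0.72 ± 0.14); neither kept its call with only the compared groups in the fit. The list tests gave adjusted p = 0.718 and 0.307. Cell cycle inhibitors (7 measured, median 0.613) had 1 gene that rose in both fits, Cdkn1c, by 1.12 ± 0.17, again not with the compared groups alone. Their camera adjusted p of 0.037 was 0.111 with an estimated correlation. It was 0.0525 without control replicate 1, 0.136 without control replicate 2, 0.0641 without Rnf2delta replicate 2, 0.112 without Rnf2delta replicate 3 and 0.0576 after quantile normalization. Of 20 imprinted genes 2 rose in both fits, Plagl1 by 1.17 ± 0.22, not with the compared groups alone (0.187; 1.7e-05 to 0.187 over the alternatives), and Cdkn1c (list median 0.311, 0.199 after quantile normalization, camera adjusted p = 0.037); with an estimated correlation adjusted p = 0.262. That call was lost without control replicate 1 (0.0551), control replicate 3 (0.158), Rnf2delta replicate 2 (0.163) or Rnf2delta replicate 3 (0.205) and after quantile normalization (0.0576). Hox genes (25 measured, Hoxd9 at 1.07 ± 0.18 in both fits, not with the compared groups alone) gave adjusted p = 0.998 and developmental transcription factors bound by Polycomb in stem cells (47 measured, 0 in both fits) 0.763, with a median of -0.00075 and a mean of 0.0527. Retinoic acid signalling gave 0.720, male germ cell differentiation 0.998, proliferation 0.763, DNA methylation and UHRF1 0.343, p53 targets and apoptosis 0.763, and immediate early and dissociation stress 0.763. Of the remaining fixed genes, Xist, the X-inactivation RNA, was at 0.87 ± 0.20 (equal-weight adjusted p = 0.0059, and 5.6e-04 to 0.25 over the alternatives), Dazl at 0.62, Ddx4 at 0.58, Cdkn2a at 0.61 (0.051, and 0.0057 to 0.387 over the alternatives), Rarb at 0.05 and Nanos2 at -0.21.

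In all, 1502 genes passed the threshold in E12.5 females with equal weights (1174 higher, 328 lower; 976 and 486 after quantile normalization). Array weights gave 254, all among them (219 higher, 35 lower), the compared groups alone 54, and 49 genes passed in all 3 fits. In simulated data with 200 changed genes, 51.0% of the equal-weight calls of this comparison were false. That share depends on how many genes truly change, so it need not hold for the 1502. Without Rnf2delta replicate 1 the equal-weight count was 843. Arrays did not overlap between the groups for 2692 genes (17.7% of those tested, where chance gives 10%).

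Male Rnf2delta germ cells at E12.5 shared part of this pattern, without Stra8. Tex101 rose by 2.88 ± 0.30 (adjusted p = 2.3e-06), Xlr by 2.13 ± 0.30 (1.4e-04), Cd63 by 2.05 ± 0.33 (6.1e-04) and Crabp1, a retinoic acid-binding protein, by 1.89 ± 0.23 (1.3e-05). Aldh1a2, an enzyme of retinoic acid synthesis, rose by 1.41 ± 0.26 (0.0027). Stra8 changed by -0.02 ± 0.35 (adjusted p = 1), Sycp3 by 0.92 ± 0.33 (0.30, and 0.0173 to 0.713 over the alternatives, passing with the compared groups blocked) and Rec8 by 0.60 (0.49). Of 40 meiotic genes 3 rose: Tex11, an X-linked meiotic gene, by 1.30 ± 0.23, and Sycp1 (1.31 ± 0.28) and Syce1 (0.91), whose calls were lost without 1 array or another. Adjusted over the list alone 9 were higher and 1 lower (median 0.142, camera adjusted p = 4.0e-05; adjusted p = 0.358 with an estimated correlation). That median was 0.214 and 0.0822 without control replicates 1 and 3, and 0.0303 and 0.249 without Rnf2delta replicates 1 and 3. Of 21 licensing genes 4 rose, of which Mael and Ddx25 lost their calls without some arrays (adjusted p up to 0.0652 and 0.0929), and 10 were higher adjusted over the list alone (median 0.482, 0.294 without Rnf2delta replicate 2, camera adjusted p = 2.2e-11; adjusted p = 0.0608 with an estimated correlation). Examples were Tex101 and Tdrd1, a piRNA pathway protein (1.80 ± 0.27, 4.1e-04). Cbx8 rose by 1.60 ± 0.18 (5.1e-06), Cdkn1c by 0.99 ± 0.17 (0.0016), Eomes, a T-box transcription factor, by 0.84 ± 0.13 (4.4e-04) and the glycolytic enzyme gene Ldha by 1.70 ± 0.25 (3.4e-04). Ddx58, a sensor of viral RNA, fell by 1.20 ± 0.17 (1.4e-04), besides Rnf2.

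Pluripotency genes in E12.5 males were 0 higher and 0 lower (median -0.0676, camera adjusted p = 0.077); their list passed without control replicate 3 (-0.107, adjusted p = 0.0401) or Rnf2delta replicate 2 (-0.0810, adjusted p = 0.0274), and 0.0274 to 0.467 was the range over the alternatives. Pou5f1 was at -0.07, Nanog at -0.06, Sox2 at 0.06, Xist at 0.47, Ddx4 at 0.36, Cdkn2a at 0.31, Dmc1 at 0.20, Rarb at 0.17, Dazl at 0.10 and Nanos2 at -0.14, none past the threshold. Early primordial germ cell genes lay lower as a list (median -0.206, -0.119 without Rnf2delta replicate 1, adjusted p = 0.0021; adjusted p = 0.206 with an estimated correlation). Retinoic acid genes lay higher (median 0.121, adjusted p = 0.012; 0.171 with an estimated correlation, 0.0593 without Rnf2delta replicate 3, where the median was 0.0522), as did imprinted genes (0.226, adjusted p = 0.0073; 0.168 with an estimated correlation, 0.0506 without control replicate 2). The imprinted median was 0.145 without control replicate 2 and 0.128 without Rnf2delta replicate 1. DNA methylation genes gave a median of 0.0906 (adjusted p = 0.017; 0.107 with an estimated correlation, 0.0566 and a median of 0.0373 without control replicate 3, 0.0862 without Rnf2delta replicate 1). PRC1, Hox, Polycomb-bound transcription factor and cell cycle inhibitor lists gave adjusted p = 0.258, 0.135, 0.138 and 0.060. Altogether 128 genes were higher and 18 lower at equal weights, 146 in all, against 285 with array weights, 139 with the compared groups alone and 253 in a fit without the 6 E12.5 female arrays, chosen after seeing the data. Leaving out control replicate 1, control replicate 2, Rnf2delta replicate 1 or Rnf2delta replicate 2 gave 78, 73, 82 and 76. The groups did not overlap for 2220 genes (14.6%, where chance gives 10%).

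At E11.5 female Rnf2delta germ cells already differed from controls, with Stra8 not among the called genes (0.07 ± 0.35, adjusted p = 1). Cd63 rose by 2.01 ± 0.33 (adjusted p = 8.7e-04), Ddah1, a dimethylarginine hydrolase, by 1.81 ± 0.22 (1.7e-05), Aldh1a2 by 1.80 ± 0.26 (1.9e-04), Hdac6, a cytoplasmic deacetylase, by 1.74 ± 0.18 (2.5e-06), and Gstm5, a glutathione transferase, by 1.61 ± 0.18 (7.7e-06). Retinoic acid signalling had 3 genes of 20 that rose, Aldh1a2, Crabp1 (1.61 ± 0.23, 1.8e-04) and Crabp2, whose call at 1.22 ± 0.28 (0.034) was lost without any of 5 of the 6 arrays; the list itself gave adjusted p = 0.083. Cbx8 rose by 1.27 ± 0.18 (1.8e-04), the single called gene of the PRC1 list (adjusted p = 0.083). Sycp3 was at 0.97 ± 0.33 (0.30, and 0.0169 to 0.814 over the alternatives, passing with the compared groups alone), Rec8 at 0.60 (0.57), Pou5f1 at 0.08 (1) and Nanog at 0.00 (1). The other fixed genes did not pass: Ddx4 was at 0.78, Xist at 0.60, Dmc1 at 0.35, Sox2 at 0.28, Rarb at 0.17, Dazl at 0.00 and Nanos2 at -0.06. Meiotic and pluripotency genes had 0 calls each and list adjusted p of 0.249 and 0.249; 1 meiotic gene was higher adjusted over the list alone. Cdkn2a, a cell cycle inhibitor silenced by PRC1 in many cell types, was at 0.93 ± 0.20 (0.023), a call that each left-out array ended.

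Imprinted genes lay higher in E11.5 females (median 0.228, camera adjusted p = 2.1e-04; adjusted p = 0.048 with an estimated correlation), with 3 called, Plagl1 (0.93), Grb10 (0.92) and Cdkn1c (0.79), each lost without some array, and 4 adjusted over the list alone. The licensing list (median 0.216, adjusted p = 0.0033; 0 called, 3 adjusted over the list alone) was lost with an estimated correlation (adjusted p = 0.344) and without control replicate 2 (0.0638). DNA methylation genes (0.236, adjusted p = 0.0061, 0.048 with an estimated correlation) lost their call without control replicate 3 (0.0536). Immediate early genes (0.159, adjusted p = 0.040, 0.344 with an estimated correlation) lost theirs without control replicate 3 (0.435), Rnf2delta replicate 1 (0.266) or Rnf2delta replicate 2 (0.0511); their median was 0.244, 0.0860 and 0.0921 without control replicates 1, 2 and 3. The genes past the threshold numbered 84 (82 higher, 2 lower), 157 with array weights, 93 with the compared groups alone and 151 without the E12.5 female arrays. Without control replicate 1, control replicate 2, Rnf2delta replicate 1 and Rnf2delta replicate 3 the counts were 41, 46, 46 and 39. Groups did not overlap for 2163 genes (14.2%, chance 10%).

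In E11.5 males the genes that rose furthest included the germ cell gene Tex101. Cd63 rose by 1.93 ± 0.33 (adjusted p = 0.0017), Tex101 by 1.83 ± 0.30 (0.0012), Ldha by 1.80 ± 0.25 (2.1e-04), Tagln2, an actin-binding protein, by 1.73 ± 0.25 (3.2e-04) and Cbx8 by 1.61 ± 0.18 (9.4e-06). Lix1 fell by 1.25 ± 0.17 (1.6e-04). Of 40 meiotic genes 3 passed, Sycp3 (1.52 ± 0.33, 0.016), Slc25a31 (1.21) and Tex11 (1.17, 0.007), and each lost its call without at least 1 array; 7 were higher adjusted over the list alone (median 0.255, camera adjusted p = 1.3e-08; adjusted p = 0.219 with an estimated correlation). Stra8 was at 0.22 ± 0.35 (1) and Rec8 at 0.30 (0.93). Cdkn2a was at 0.69 (0.15, and 0.0267 to 0.423 over the alternatives, passing with array weights, with the compared groups alone or blocked, and without the E12.5 female arrays) and Dmc1 at 0.65 (0.38, and 0.0496 with the compared groups blocked). Ddx4 was at 0.67, Dazl at 0.43, Sox2 at 0.27, Nanos2 at 0.22, Rarb at 0.17, Xist at 0.02, Nanog at -0.12 and Pou5f1 at -0.16, with none past the threshold. Of 21 licensing genes 5 passed, 10 were higher and 1 lower adjusted over the list alone, and the list kept its call with an estimated correlation (median 0.428, 0.232 without Rnf2delta replicate 3; adjusted p = 1.7e-10, and 0.042). Tdrd1 (1.30 ± 0.27, 0.014) and Mael (1.28, 0.0083) were among them but lost their calls without some arrays.

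Cell cycle inhibitors lay higher as a list in E11.5 males (median 0.284, adjusted p = 0.0014, 0.026 with an estimated correlation) with 0 called and 3 adjusted over the list alone, and imprinted genes did too (0.189, adjusted p = 0.0014; 0.083 with an estimated correlation; median 0.125 and adjusted p = 0.0740 without Rnf2delta replicate 1). Early primordial germ cell genes lay lower (-0.206, adjusted p = 0.0048; 0.260 with an estimated correlation), a call lost without control replicate 1 (0.103), Rnf2delta replicate 2 (0.0540) or Rnf2delta replicate 3 (0.0628, median -0.0947); 1 was called, the LIM homeobox gene Lhx1 (-0.97 ± 0.22, 0.023, lost without some arrays, and -0.61 without Rnf2delta replicate 1). DNA methylation genes (0.0668, adjusted p = 0.019, 0.0776 with an estimated correlation) changed sign without control replicate 3 (-0.0167, 0.0729) and lost the call without Rnf2delta replicate 1 (0.00662, 0.0600). Their median was 0.143 and 0.107 without control replicates 1 and 2, 0.111 and 0.124 without Rnf2delta replicates 2 and 3, and 0.0343 with no filter on dim probe sets. The pluripotency list (-0.0627, adjusted p = 0.177, and 0.0086 to 0.622 over the alternatives) passed without Rnf2delta replicate 1 (-0.0944, adjusted p = 0.0086). With 109 genes past the threshold (103 higher, 6 lower), array weights gave 344, the compared groups alone 150 and the fit without E12.5 female arrays 228. The replicate number as a block with the compared groups alone, which takes same-numbered arrays as pairs, gave 236. Counts without control replicate 2, control replicate 3 and Rnf2delta replicate 3 were 52, 62 and 50. Arrays of the groups did not overlap for 2363 genes (15.6%, chance 10%).

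**Figure D2:**
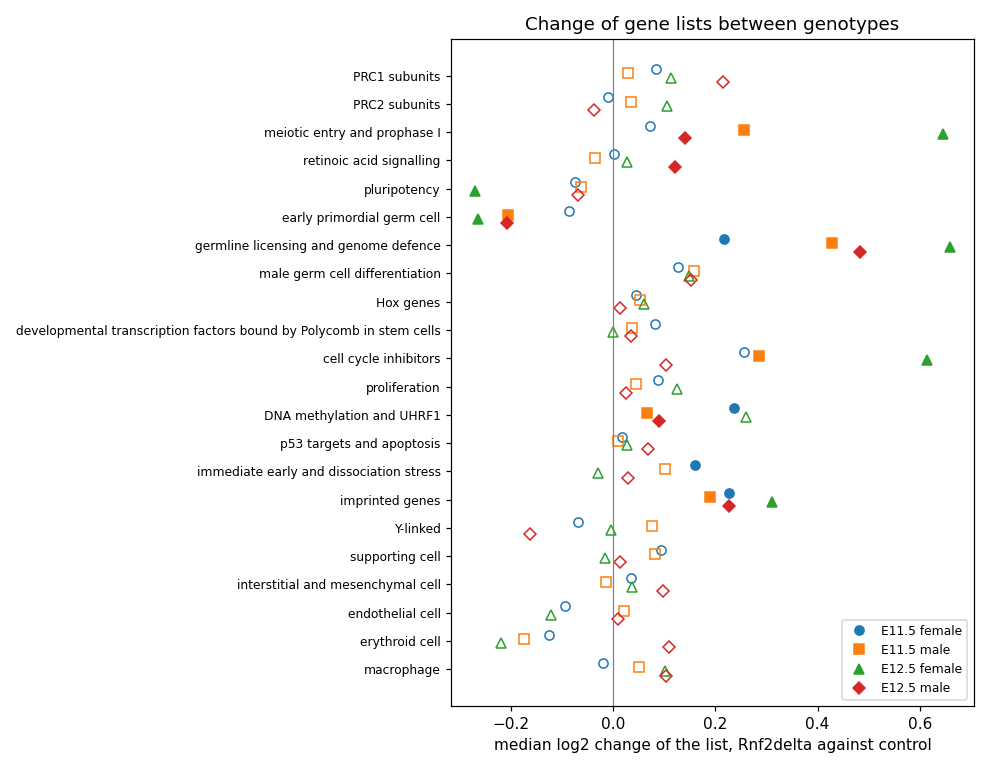
Median log2 change of each of 22 gene lists (horizontal axis, Rnf2delta minus control) in the 4 genotype comparisons, filled where the camera adjusted p with a preset correlation was under 0.05. The meiotic list lay at 0.645 in E12.5 females, 0.142 in E12.5 males, 0.255 in E11.5 males and 0.0717 in E11.5 females.

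The genotype effect at E12.5 was then tested for a difference between the sexes. Stra8 gained 2.81 ± 0.50 more in females than in males (limma adjusted p = 0.013), a call lost only with the compared groups alone in the fit. Vaultrc5 and Rny3 differed by -2.73 and -2.02, and these 3 genes passed in both fits. With equal weights 45 genes differed (33 higher, 12 lower; 26 and 19 after quantile normalization), with array weights 5 and with the compared groups alone 1. Meiotic genes gained more in females as a list (median 0.523, camera adjusted p = 1.2e-06) and pluripotency genes less (-0.154, 0.0062); with an estimated correlation both gave adjusted p = 0.749. The count was 7, 29 and 25 without control male replicates 1, 2 and 3, 26 and 10 without Rnf2delta male replicates 2 and 3, 313 and 77 without control female replicates 2 and 3, and 22, 78 and 259 without Rnf2delta female replicates 1, 2 and 3. At E11.5 limma called 0 genes whose genotype effect differed between the sexes, with 269 at an unadjusted p under 0.05 and 0 by array weights or by the compared groups alone. The 5 with the smallest p were Trim21 (-1.16 ± 0.23, adjusted p = 0.31), Lix1 (0.96), Ptpru (0.83), Cltb (-0.77) and Olfr554 (0.74). As lists, meiotic genes (-0.170, camera adjusted p = 3.4e-05) and licensing genes (-0.273, 0.0010) gained less in females than in males at E11.5; adjusted p = 0.986 with an estimated correlation for both.

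Between E11.5 and E12.5 the female genotype effect grew for Stra8 by 2.72 ± 0.50 (limma adjusted p = 0.018), a call lost with the compared groups alone (0.254) and without control E11.5 replicate 2 (0.061) or Rnf2delta E12.5 replicate 1 (0.057). Meioc gained 2.48, and n-R5s136, a 5S ribosomal RNA, changed by -2.62; these 3 genes passed in both fits. Equal weights called 22 genes (15 higher, 7 lower; 18 and 13 after quantile normalization), array weights 6 and the compared groups alone 0, with limma throughout. The meiotic list grew by 0.651 (camera adjusted p = 7.5e-14), the licensing list by 0.654 (2.9e-05), and the pluripotency list changed by -0.191 (2.4e-04); with an estimated correlation each gave adjusted p = 0.384. Early primordial germ cell genes changed by -0.173 (0.023; 0.0687 with array weights, 0.70 with an estimated correlation). Leaving out control E11.5 replicate 2 gave 4 genes, Rnf2delta E11.5 replicate 1 gave 11, control E12.5 replicates 2 and 3 gave 113 and 54, and Rnf2delta E12.5 replicates 1, 2 and 3 gave 8, 35 and 126. In males limma called 0 genes whose genotype effect differed between the stages, with 361 at an unadjusted p under 0.05 and 0 by the other 2 fits; the smallest p belonged to Tex19.2 (0.93), Atmin (0.93), Lix1 (0.87), Trabd (0.72) and Cd300c (0.61), all at adjusted p = 1.

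A group of genes was higher in Rnf2delta in all 4 genotype comparisons. With equal weights they numbered 27, and with array weights 29. Cd63 led with 1.93 to 3.29, and Gstm5 (1.60 to 2.21), Ddah1 (1.59 to 1.81) and Ldha (1.44 to 1.80) were among the others. The set also held Cbx8 (1.23 to 1.61), Crabp1 (0.95 to 1.89), Zic2, a zinc finger transcription factor (1.03 to 1.42), and Igf1r (1.03 to 1.37) and Igfbp2 (1.12 to 1.39), which encode a receptor and a binding protein of insulin-like growth factors. No gene was lower in all 4. In exactly 3, 2 and 1 comparisons 45, 65 and 1114 genes were higher and 2, 5 and 338 lower with equal weights, against 60, 107 and 376 higher and 4, 10 and 122 lower with array weights. At E11.5 the changes of the sexes, which share no arrays, correlated across all genes with r = 0.539 and Spearman's rho = 0.391 (jackknife SE of r over arrays 0.0498; genes are not independent replicates), and 45 genes were higher in both against 0.556 if independent. At E12.5 the values were r = 0.317, rho = 0.189 and SE 0.0977, with 86 genes against 9.90, and 65 against 3.52 with array weights.

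Markers of other gonadal cells were measured in the same comparisons. In E12.5 females supporting cell genes (18 measured) had a median of -0.0146 and a mean of 0.0561 (camera adjusted p = 0.798), interstitial and mesenchymal genes (12) 0.0369 (0.763), endothelial genes (9) -0.122 (0.718), erythroid genes (5) -0.219 (0.307) and macrophage genes (10) 0.101 (0.798). Y-linked genes (3) gave -0.00399, and the steroidogenic list held 2 measured genes, too few for a test: Star at 0.22 ± 0.13 (limma adjusted p = 0.305) and Cyp11b1 at -0.12 ± 0.14 (0.656). None of the 6 tested lists of other cells or of the Y chromosome passed in the other genotype comparisons either, by the preset correlation and equal weights. With the replicate number as a block, which takes same-numbered arrays as pairs, the erythroid list was lower in E11.5 males (camera adjusted p = 0.0231). On Rnf2delta E12.5 male replicate 3, the embryonic globin genes Hbb-y and Hba-x read 9.71 and 4.0, against means of 2.02 and 2.26 on the other 29 arrays.

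How far the genotype changes followed normal development was measured against control stages that share no array with them. Across 15180 genes the E12.5 female change correlated with the control change from E11.5 to E13.5 in females with r = 0.340 and rho = 0.284 (jackknife SE 0.177), and 542 genes were higher in both against 167 if independent. By array weights, 147 of the 219 genes higher in E12.5 females were also higher at E13.5 than at E11.5 in control females (36.4 if independent) and 8 lower (31.5). The E11.5 female change correlated with the control step from E12.5 to E13.5 with r = 0.237 (rho = 0.208, SE 0.0572), with 43 genes higher in both against 13.9. Males gave r = 0.130 at E12.5 (rho = 0.0861, SE 0.0869; 35 genes against 6.81) and 0.248 at E11.5 (rho = 0.170, SE 0.102; 12 against 0.780). Genes are not independent replicates in these 4 correlations. On an axis running from 0 at control E11.5 to 1 at control E13.5, built from 3992 genes in females, E12.5 controls stood at 0.460 ± 0.135 and Rnf2delta at 0.705 ± 0.15 (SD, n = 3; two-sided exact permutation p = 0.1, the smallest that 3 against 3 arrays allow). The difference of 0.245 was 0.157 without Rnf2delta replicate 1. In males, over 1664 genes, the positions were 0.531 ± 0.0517 and 0.625 ± 0.0641 (two-sided exact permutation p = 0.2).

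**Figure D3:**
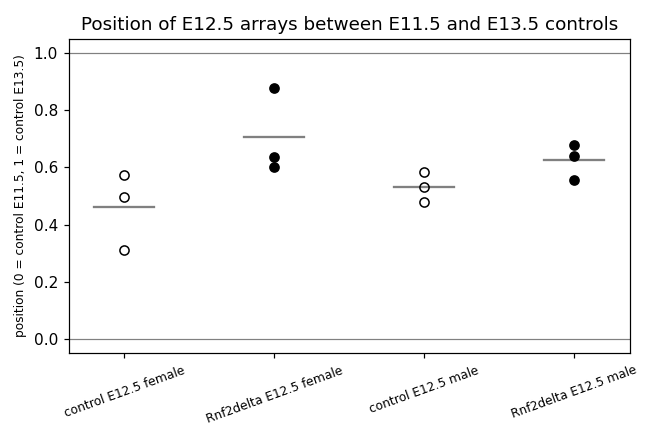
Position of each E12.5 array (vertical axis, no unit) by group (horizontal axis) between the control E11.5 mean at 0 and the control E13.5 mean at 1, with a bar at each group mean. Female controls lay at 0.311 to 0.574 and female Rnf2delta arrays at 0.603 to 0.877.

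The sexes were compared in controls at each stage. At E11.5 the called genes included those of the Y chromosome: Uba1y differed by -5.35 ± 0.19 (female minus male; limma adjusted p = 8.9e-18), Eif2s3y by -3.23 ± 0.20 (9.0e-12) and Kdm5d by -1.39 ± 0.16 (1.7e-05). All 3 measured genes of the Y-linked list were lower (median -1.39, camera adjusted p = 5.6e-18; adjusted p = 1.2e-06 with an estimated correlation). Porcn, an X-linked gene of Wnt secretion, was higher in females by 1.70 ± 0.33 (0.023), and Lhx1 was lower (-1.22 ± 0.22, 0.010), calls that were lost without some arrays. No other list passed; meiotic genes had 0 calls (median -0.00169, mean 0.00699, adjusted p = 0.660). In total 17 genes were higher and 21 lower in females (25 and 17 after quantile normalization), with 117 called by array weights, 32 by the compared groups alone and 86 without the E12.5 female arrays. The count of 38 was 23, 4 and 9 without male replicates 1, 2 and 3 and 15, 4 and 21 without female replicates 1, 2 and 3. Groups did not overlap for 2471 genes (16.3%, chance 10%).

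By E12.5 the 2 sexes of the controls differed in genes of several kinds. Zglp1 was higher by 1.76 ± 0.23 (limma adjusted p = 2.8e-06), Gata2, a GATA transcription factor, by 1.77 ± 0.18 (1.1e-07), Id2, an inhibitor of DNA binding, by 2.28 ± 0.32 (1.1e-05), Phlda2, an imprinted gene, by 3.42 ± 0.40 (6.9e-07) and Porcn by 3.63 ± 0.33 (2.6e-08). Lower in females were Lefty1, a Nodal antagonist (-3.28 ± 0.34, 1.2e-07), Tdgf1, a Nodal co-receptor (-2.68 ± 0.39, 1.9e-05), and Pmaip1, a proapoptotic gene (-1.85 ± 0.28, 2.2e-05). Meiotic genes went both ways: with array weights 4 were higher and 2 lower in females, such as Dmc1 (0.91 ± 0.25, 0.0097) and Hormad1 (0.96 ± 0.20, 0.0011), and the list gave adjusted p = 0.056. Male germ cell differentiation genes counted 2 higher and 6 lower with array weights (list adjusted p = 0.103). Proliferation genes counted 1 higher and 8 lower (list adjusted p = 0.108), with the mitotic checkpoint gene Bub1b at -1.0 ± 0.15. Imprinted genes lay higher in females (median 0.248, adjusted p = 0.0063; adjusted p = 0.235 with an estimated correlation), and so did developmental transcription factors (0.0395, adjusted p = 0.023; 0.241 with an estimated correlation). The Y-linked list was lower (-1.18, adjusted p = 4.5e-05; 0.0056 with an estimated correlation). Equal weights called 2892 genes (654 higher and 2238 lower in females; 864 and 1744 after quantile normalization), array weights 1876 and the compared groups alone 1150; 1863 passed in the first 2 fits. Small RNAs were among them, with Rny1 higher in females by 3.27 ± 0.30 and n-R5s136 by 3.57 ± 0.35, and 4353 genes did not overlap (28.7%, chance 10%).

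At E13.5 meiotic genes separated the sexes. Stra8 was higher in females by 3.93 ± 0.35 (limma adjusted p = 7.7e-09), Meioc by 3.45 ± 0.27 (7.1e-10), Rec8 by 2.70 ± 0.26 (2.1e-08), Sycp3 by 1.69 ± 0.33 (4.7e-04) and Dmc1 by 1.46 ± 0.25 (1.0e-04). Of 40 meiotic genes 20 were higher and 0 lower in females (25 and 1 adjusted over the list alone; median 0.651, camera adjusted p = 2.2e-12; adjusted p = 0.136 with an estimated correlation). Lower in females were Nanos2, which directs male germ cell fate (-2.50 ± 0.26, 7.1e-08), Lefty1 (-3.73 ± 0.34, 8.3e-09), Tdgf1 (-3.69 ± 0.39, 1.2e-07) and the homeobox gene Otx2 (-2.43 ± 0.23, 1.6e-08). Of 15 measured male differentiation genes, 8 of which other lists also hold, 7 were lower in females and 1 higher, in both adjustments (median -0.249, adjusted p = 2.6e-05; 0.0045 with an estimated correlation). The higher one was Cited1, by 2.6 ± 0.38. Pluripotency genes counted 1 higher and 11 lower in females (1 and 13 adjusted over the list alone), with Nanog at -0.97 ± 0.20 (0.0011) and Utf1 at -1.20 ± 0.17 (median -0.407, adjusted p = 3.6e-06; 0.136 with an estimated correlation). Imprinted genes split 7 to 2, with Phlda2 at 3.84 ± 0.40 and Mest at -2.33 ± 0.23 (adjusted p = 0.011; 0.178 with an estimated correlation). Cbx8 was higher in females by 1.57 ± 0.18 (3.6e-07) and Rhox6, an X-linked homeobox gene, by 2.51 ± 0.21 (1.9e-09). The comparison called 2471 genes, 1200 higher and 1271 lower in females, and 5462 genes did not overlap (36.0%, chance 10%).

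Control females from E11.5 to E13.5, a comparison chosen after seeing the data, gained meiotic and licensing genes and lost pluripotency genes. Stra8 rose by 4.06 ± 0.35 (limma adjusted p = 3.0e-09), Rec8 by 3.12 ± 0.26 (1.5e-09), Zglp1 by 2.89 ± 0.23 (5.4e-10), Sycp3 by 2.27 ± 0.33 (5.9e-06) and Dazl, an RNA-binding protein of licensed germ cells, by 1.77 ± 0.25 (5.1e-06). Tdgf1 fell by 4.29 ± 0.39 (6.8e-09), Nanog by 2.09 ± 0.20 (1.6e-08), Nanos3 by 1.60 ± 0.23 (7.0e-06) and Esrrb by 1.54 ± 0.20 (1.5e-06). Of 40 meiotic genes 31 rose and 0 fell, of 21 licensing genes 15 and 0, and of 29 pluripotency genes 0 and 19. Adjusted over the list alone 33, 15 and 0 rose and 0, 0 and 19 fell. Their medians were 1.07, 0.931 and -0.679 (camera adjusted p = 8.7e-18, 9.2e-09 and 5.1e-11; with an estimated correlation adjusted p = 0.064, 0.064 and 0.057). Cbx8 rose by 1.97 ± 0.18 (5.9e-09) and Rnf2 by 0.96 ± 0.19 (2.6e-04), among 7 PRC1 genes higher and 4 lower. The count was 3992 genes (2163 higher and 1829 lower at E13.5), 3866 of them without overlap between the arrays, and 6254 of all genes did not overlap (41.2%, chance 10%). By steps, E12.5 exceeded E11.5 in Dazl (1.64 ± 0.25), Ddx4 (1.59 ± 0.25), Zglp1 (2.26 ± 0.23) and Dmc1 (1.23 ± 0.25), and Stra8 (3.38 ± 0.35), Meioc (2.90 ± 0.27) and Rec8 (2.10 ± 0.26) rose from E12.5 to E13.5. The first step called 2853 genes with equal weights (692 higher, 2161 lower; 1054 and 1674 after quantile normalization), 1604 with array weights and 926 with the compared groups alone, and the second 3309 (2579 higher, 730 lower), 2184 and 1461. Groups did not overlap for 4135 genes in the first step (27.2%) and 4589 in the second (30.2%).

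Control males over the same days raised genes of the male path. Nanos2 rose by 2.52 ± 0.26 from E11.5 to E13.5 (limma adjusted p = 1.8e-07), Bnc2, a zinc finger gene, by 3.50 ± 0.28 (1.7e-09), Pmaip1 by 3.04 ± 0.28 (1.7e-08), Hesx1 by 2.49 ± 0.18 (4.4e-10), Otx2 by 1.84 ± 0.23 (3.1e-06) and Rnf2 by 1.10 ± 0.19 (1.7e-04). Rhox6 fell by 2.66 ± 0.21 (1.7e-09) and Esrrb by 1.13 ± 0.20 (3.4e-04). Of 15 male differentiation genes 4 rose and 0 fell, also adjusted over the list alone (median 0.330, camera adjusted p = 0.0037; 0.056 with an estimated correlation). Meiotic genes counted 7 that rose, Sycp1 (1.41 ± 0.28) among them, and 10 adjusted over the list alone (median 0.356, adjusted p = 1.4e-05; 0.345 with an estimated correlation), while Stra8 stayed at 1.85 to 2.40 on every array outside E12.5 and E13.5 females. Early primordial germ cell genes counted 1 that rose and 8 that fell (median -0.366, adjusted p = 2.8e-04; 0.169 with an estimated correlation). The count was 1664 (808 higher and 856 lower at E13.5; 1637 of them without overlap), 2891 with array weights and 2497 with the compared groups alone, and 1108, 1049 and 1102 without E11.5 replicate 2, E13.5 replicate 2 and E13.5 replicate 3; 5135 genes did not overlap (33.8%, chance 10%). From E11.5 to E12.5, where Pmaip1 rose by 1.86 ± 0.28 and the microglial and macrophage gene Tyrobp fell by 1.32 ± 0.24, 397 genes passed (146 higher, 251 lower; 215 and 218 after quantile normalization), 1241 with array weights, 781 with the compared groups alone and 907 without the E12.5 female arrays. That count was 149, 177 and 160 without E11.5 replicates 1, 2 and 3 and 184 and 104 without E12.5 replicates 2 and 3. From E12.5 to E13.5, where Nanos2 rose by 1.99 ± 0.26 and Kit, the receptor for stem cell factor, fell by 0.91 ± 0.14, 167 genes passed (115 higher, 52 lower), 456 with array weights, 242 with the compared groups alone and 330 without the E12.5 female arrays. It was 84, 92 and 104 without E12.5 replicates 1, 2 and 3 and 60 and 103 without E13.5 replicates 2 and 3. The macrophage list fell in the first step (median -0.324, adjusted p = 3.1e-04; 0.428 with an estimated correlation), and groups did not overlap for 3823 genes in the first step (25.2%) and 2927 in the second (19.3%).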

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

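Chosen only after the result was seen were the tests of an intermediate stage, of a shared property of the E12.5 female libraries, of somatic cells and of the share of other gonadal cells, the count over other choices of 9 arrays, and the comparison of E13.5 with E11.5 controls; the tests of older litters, of the spread of controls and of other splits of the arrays were set beforehand.

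Genes whose genotype effect differed between the sexes at E12.5 numbered 45, and chance is not excluded. Of 100 splits of the arrays 19 gave as many, and the highest gave 985. Each split exchanged the arrays of the 2 sexes separately and left the genotype effect in the data. A split that keeps or reverses the true labels of 1 sex still holds its genotype effect, so the splits decide nothing. Higher in females than in males were the effects on Stra8 (2.81), Aldh3b3 (2.34), Crabp2 (2.09), Meioc (2.03), 1700013H16Rik (1.80), Tspyl2 (1.63), Usp31 (1.62), Setdb2 (1.5), Gkap1 (1.39) and Mir505 (1.4). Lower were those on Bsx (-0.86), Snora3 (-0.87), Sost (-0.96), G630025P09Rik (-0.98), Snora21 (-1.26), Gm12238 (-1.36), Snora52 (-1.38), Rny1 (-1.87), Rny3 (-2.02) and Vaultrc5 (-2.73). The meiotic and pluripotency lists differed by 0.523 and -0.154 in median log2 change (with an estimated correlation adjusted p = 0.749 for both). At E11.5 the meiotic and licensing lists differed by -0.170 and -0.273 (adjusted p = 0.986 for both with an estimated correlation), with 0 single genes called by limma (269 at an unadjusted p under 0.05, 0 with array weights or the compared groups alone). With a count of 0 each of the 100 splits gives at least as many, so the splits (highest 21) decide nothing.

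Genes whose genotype effect differed between E11.5 and E12.5 in females numbered 22. Chance is not excluded here either. Of 100 splits 14 gave as many and the highest gave 657, but these splits too left the genotype effect in the data and decide nothing. The effect grew for 1700013H16Rik (2.76), Stra8 (2.72), Meioc (2.48), Usp31 (1.99), Nkrf (1.71), Tspyl2 (1.68), Gm10033 (1.34), Cenpk (1.27), Dcaf6 (1.25) and Ikzf5 (1.24). It was lower at E12.5 for Snora3 (-0.88), Snora21 (-1.35), Camkv (-1.41), Rny3 (-1.62), Gm12238 (-1.64), Vaultrc5 (-2.43) and n-R5s136 (-2.62). The lists of meiotic, licensing, pluripotency and early primordial germ cell genes differed by 0.651, 0.654, -0.191 and -0.173. With an estimated correlation the first 3 gave adjusted p = 0.384 and the last 0.70 (0.0687 with array weights). In males the erythroid list differed by 0.343 between the stages (camera adjusted p = 0.011, 0.213 with array weights, 0.135 with an estimated correlation). Its 5 measured genes averaged 4.28 on Rnf2delta E12.5 male replicate 3, against 2.25 and 2.33 on replicates 1 and 2 of that group. Between the stages in males limma called 0 genes (361 at an unadjusted p under 0.05, 0 in the other fits). The 100 splits (highest 73) again decide nothing beside a count of 0.

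Outside the named genes, 479 of 9784 probe sets with no single symbol passed in E12.5 females with equal weights, 232 higher and 247 lower in Rnf2delta, and 2 were higher in E11.5 males. For genes, 51.0% of such calls in E12.5 females were false in simulated data with 200 changed genes. That share need not hold for these probe sets. Each comparison of 3 with 3 arrays has only 10 splits, too few for a share under 0.05. The real split gave the highest count in each (1 of 10). The genotype comparisons gave 84 (highest other split 1) in E11.5 females, 109 (1) in E11.5 males, 1502 (471) in E12.5 females and 146 (0) in E12.5 males. Sex comparisons gave 38 (0), 2892 (20) and 2471 (0) at E11.5, E12.5 and E13.5, and the stage steps 2853 (69) and 3309 (3) in females and 397 (0) and 167 (2) in males.

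Meiotic genes were higher in Rnf2delta E12.5 females by a median of 0.645. The spread of the control arrays alone stays undecided as the cause. Of 40 meiotic genes, 19 had all 3 mutant arrays above all 6 control arrays of E11.5 and E12.5 females (47.5%, against 5.69% of all genes). The gaps ran from small (Mei1, 2.59 against 2.57 on the highest control array) to large (Meioc, 4.43 against 2.52). Sycp2, Mei1 and Majin each had a mutant array under the 60th percentile of the E12.5 female arrays (3.05). Of the 84 choices of 3 of these 9 arrays, the next highest gave 4. However, 3 of the 9 are of an earlier stage, and meiotic genes rose with stage in control females. That low count was thus partly fixed in advance. The 6 E12.5 arrays alone make too few splits for a share under 0.05. A different share of other gonadal cells as the whole cause would move lists of germ cell genes alike. The meiotic and pluripotency medians instead lay 0.915 apart in opposite directions, at 0.420 to 0.759 and -0.412 to -0.215 without 1 array. That does not settle it, since the criterion was written after these medians were seen and no pluripotency gene fell in both fits. With an estimated correlation both lists gave camera adjusted p = 0.111. RNA of somatic cells is not excluded by their markers, since 24 of 30 stayed under the 60th percentile of these arrays (3.05) in both genotypes, and their list medians of -0.0146 and 0.0369 decide nothing. Older Rnf2delta litters stay open, and the criterion set beforehand for them was met. Over 965 genes that develop in both sexes, meiotic list left out, E12.5 male mutants stood 0.135 further along the axis than controls (0.544 ± 0.057 and 0.679 ± 0.0652, SD, n = 3). Female mutants stood 0.231 further, and each difference exceeded the SD of either group. An earlier start of the female programme in Rnf2delta, the hypothesis the design names, may give the female value. By itself it does not predict the male one.

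The 6 E12.5 female arrays stood apart from the other 24 in their correlation with their own group. A plain intermediate between E11.5 and E13.5 stays undecided. In control females 5.22% of genes had an E12.5 mean more than 0.5 beyond the range of those stages, 18.4 times the share in males (0.283%). A wider spread of arrays raises such a share by itself. The median within-group SD was 0.238 in E12.5 control females and 0.149 in E12.5 control males. A property shared by the libraries of both genotypes, such as amplification yield, may account for the arrays standing apart. It stays open, as does a stage-specific state of female germ cells. Deviations from the midpoint correlated across genes with r = 0.404 between the genotypes, which decides nothing, since both share that midpoint and males, whose arrays did not stand apart, gave 0.397 (genes are not independent replicates). Mean small RNA signal was not shared: it exceeded the highest of the other 24 arrays (3.63) on 3 of the 6 arrays, and group means were 3.69 in controls and 3.39 in Rnf2delta.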

How the results depend on the processing

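Chosen after the data were seen were the fit without the 6 E12.5 female arrays, the comparison of E13.5 with E11.5 controls, array weights in the list tests, and the fits without small RNA genes and without 1 array for the E12.5 male lists; the other alternatives were set beforehand. No gene called in any comparison and named by the rule changed direction under any alternative. Where the arrays did not overlap, leaving out 1 array could not reverse a gene, so that part was fixed in advance. In E12.5 females 63 genes kept their call in 912 settings and lost it in 209, and in E12.5 males 35 genes in 541 and 86. The numbers were 298 and 44 for 19 genes in E11.5 females, and 387 and 80 for 26 genes in E11.5 males. Named genes that had no call gained one in 2 settings in E11.5 females (Sycp3), 5 in E11.5 males (Cdkn2a and Dmc1), 7 in E12.5 females (Nanog and Cdkn2a) and 1 in E12.5 males (Sycp3). Signal near the array's lower end limits what can be seen, and 3 arrays per group limit the precision. The cause was not tested for the changes that follow, except that a minimum of 1.5-fold and the removal of arrays leave fewer calls or samples by construction.

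Array weights gave 157, 344, 254 and 285 genes between genotypes (E11.5 females, E11.5 males, E12.5 females, E12.5 males), 117 and 1876 between the sexes at E11.5 and E12.5, 1604 and 2184 for the female steps, 1241 and 456 for the male steps, 2891 for E13.5 against E11.5 males, and 5 and 6 for the interactions at E12.5 and in females. With only the compared groups in the fit the counts were 54 in E12.5 females, 1150 between the sexes at E12.5, 926 and 1461 for the female steps, 781 for the first male step, 2497 for males from E11.5 to E13.5, 1 for the sex interaction at E12.5 and 0 for the stage interaction in females. Without the 6 E12.5 female arrays the counts were 151, 228 and 253 in E11.5 females, E11.5 males and E12.5 males, 86 between the sexes at E11.5, and 907 and 330 for the male steps. Requiring 1.5-fold gave 1899 between the sexes at E12.5, 1825 and 2128 for the female steps and 2636 for females from E11.5 to E13.5. Without small RNA genes E12.5 females gave 1446.

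The replicate number as a block with only the compared groups gave 93, 236, 86 and 199 genes between genotypes in E11.5 females, E11.5 males, E12.5 females and E12.5 males, and over all arrays 83, 116, 1478 and 144. Of 12 Rnf2delta arrays, each with 3 controls to match, 10 correlated best with the control of their own number. The exceptions were replicates 2 and 3 of E11.5 females. This is a hint from the data that possible pairs are not limited to E11.5 males, but r ran from -0.140 to 0.293 and 6 of 12 pairs exceeded 0.1. In E11.5 males, where the numbers were taken as possible pairs, the block changed the erythroid list's call (camera adjusted p = 0.023, lower) and no other list's.

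With an estimated correlation the meiotic list lost its call in E11.5 males (0.255, p = 0.219), E12.5 females (0.645, 0.111) and E12.5 males (0.142, 0.358), as did pluripotency in E12.5 females (-0.269, 0.111); in E12.5 males pluripotency passed with the compared groups alone (-0.0676, 0.0437). Over genes past the threshold in the developmental comparison alone, the correlations with later development moved to 0.308 in E11.5 females, 0.272 in E12.5 males and 0.618 in E11.5 males, and those between the sexes to 0.649 at E11.5 and 0.451 at E12.5.

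Leaving out 1 array gave 39 to 62 genes in E11.5 females, 50 to 99 in E11.5 males, 843 to 1925 in E12.5 females and 73 to 150 in E12.5 males. Sex comparisons gave 4 to 23, 2121 to 3105 and 1750 to 2001 at E11.5, E12.5 and E13.5. The steps gave 2061 to 3009 and 2353 to 3420 in females and 104 to 287 and 60 to 150 in males, and E13.5 against E11.5 gave 3055 to 3443 and 1049 to 1211. The interactions gave 7 to 313 (sex, E12.5), 4 to 126 (stage, females) and 0 to 0 for the other two. The meiotic list ranged from 0.0449 to 0.101 in E11.5 females, 0.172 to 0.346 in E11.5 males, 0.420 to 0.759 in E12.5 females and 0.0303 to 0.249 in E12.5 males. Pluripotency ranged from -0.118 to -0.0104 in E11.5 females, -0.0944 to -0.0593 in E11.5 males, -0.412 to -0.215 in E12.5 females and -0.111 to -0.0236 in E12.5 males, and the axis difference from 0.157 to 0.301 in females and 0.0659 to 0.131 in males.

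Values under the threshold that changed sign were Nanog (0.00257; -0.0229 after quantile normalization, -0.0501 with array weights, -0.143 to 0.0833 without 1 array), Dazl (0.00137; -0.0279 after quantile normalization, -0.309 to 0.265), Ring1 (-0.0451 to 0.127), Pou5f1 (-0.0454 to 0.194), Stra8 (-0.0273 to 0.233) and Nanos2 (-0.179 to 0.0145) in E11.5 females. In E11.5 males they were Xist (-0.144 to 0.122) and Nanog (-0.321 to 0.0287), in E12.5 females Rarb (-0.0539 to 0.152) and Ring1 (-0.281 to 0.101), and in E12.5 males Pou5f1 (-0.210 to 0.0495), Sox2 (-0.0725 to 0.279), Stra8 (-0.0658 to 0.0713) and Nanos2 (-0.288 to 0.0715). A called list changed sign too: DNA methylation in E11.5 males (0.0668, adjusted p = 0.019) was at -0.0167 without control replicate 3, and at -0.0167 to 0.143 over the left-out arrays.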

Other observations

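The tests of an erythroid source and the comparison of E13.5 with E11.5 controls were chosen after the result was seen; the test of a poor array was set beforehand.

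Polycomb subunits moved apart during control development. In females from E11.5 to E13.5, Yaf2 and Kdm2b, subunits of variant PRC1, rose by 1.40 ± 0.20 (SE; limma adjusted p = 5.3e-06) and 1.23 ± 0.14 (5.0e-07), and Phf19, a PRC2 accessory subunit, by 0.77 ± 0.18 (0.0023). Jarid2 and Mtf2, other accessory subunits of PRC2, fell by 0.86 ± 0.15 (1.2e-04) and 0.95 ± 0.17 (1.3e-04). Of 19 PRC1 genes 7 rose and 4 fell (8 and 4 adjusted over the list alone; median 0.164, camera adjusted p = 0.096), and of 11 PRC2 genes 3 rose and 4 fell in both adjustments (median -0.0356, 0.658). In males Phf19 fell by 1.29 ± 0.18 (2.4e-05) and Jarid2 by 0.76 ± 0.15 (0.0016). Phf19 thus stood 2.32 ± 0.18 higher in E13.5 females than males (7.1e-10), while Mtf2 (-0.80 ± 0.17, 0.0014) and Phc1, a PRC1 scaffold subunit (-0.85 ± 0.13, 6.7e-05), were lower in females.

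Immediate early genes fell in females over the same days, 5 of 16 and none the other way, in both adjustments (median -0.301, camera adjusted p = 0.0048; adjusted p = 0.225 with an estimated correlation). Examples were Ier3 by 1.15 ± 0.17 (1.3e-05) and Dusp1, a phosphatase, by 1.02 ± 0.23 (0.0013). Cell cycle inhibitors went both ways: Cdkn2d rose by 1.37 ± 0.20 (1.3e-05) and Cdkn1c by 1.22 ± 0.17, while Cdkn1b fell by 1.79 ± 0.43 (0.0024), and the list gave adjusted p = 0.068. In males the list lay higher (median 0.412, adjusted p = 0.0058; 0.056 with an estimated correlation), and endothelial markers lay lower (-0.213, adjusted p = 0.032; 0.169 with an estimated correlation).

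On Rnf2delta E12.5 male replicate 3 the embryonic globin gene Hbb-y read 9.71, 18.2 SD above the mean of the other 29 arrays, and Hba-x 4.0, 8.12 SD above. Of the 5 measured erythroid genes 2 exceeded 3 SD. The other 3, Alas2, Slc4a1 and Klf1, read 2.79, 2.49 and 2.38, under the 60th percentile of that array (3.09), where differences are compressed, so erythroid RNA may be the source and stays open, although the sort for GFP selects against whole erythroid cells. The criterion first written, which took 2 or fewer genes to argue against that source, was dropped for this reason. A poor array stays undecided, because the interquartile range of its relative log expression was 0.290, against a median of 0.288 over 24 arrays, where it ranked 12. By other measures it was the lowest of these 24, with an array weight of 0.512 (the next was 0.850) and a mean correlation of 0.983 with its own group. No biological explanation was tested.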
